A study of Mus musculus with 8 samples.

How the data were processed

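The 8 samples are 6 RNA-seq libraries, 3 of WT (Tet3 f/f) and 3 of KO preadipocytes, and 2 WGBS pools, 1 per genotype. Groups and library numbers were taken from the sample labels. Per the labels' protocols, cells were sorted from the stromal vascular fraction of inguinal fat, RNA was selected by poly(A), and DNA was converted with bisulfite before library construction. The submitters' processing notes list Trim Galore 0.6.6, Bismark 0.23.0, HISAT2 2.2.1, HTSeq 0.9.1 and DESeq2 1.36.0, and the builds GRCm39, mm39 and mm10, without saying which was used for which step.

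The RNA table holds raw read counts per gene symbol as deposited, without normalization. It lists 35976 symbols, 20133 of them at 0 in every library, and it has no row of unassigned reads. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The WGBS table is the authors' deposited table of regions with their length, number of CpGs, difference of mean methylation between a first and a second group and a summed test score per the file headers. The caller and thresholds are not given in the sources used here. The table has 2 columns of per-group mean levels whose names match no sample, and these were not used.

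Counts were tested with edgeR 4.0.16 in R 4.3.3 under limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 9943 genes holding at least 99.2% of the counts of each library, and library sizes were recomputed over them. TMM factors were used, with a quasi-likelihood test of KO against WT and Benjamini-Hochberg adjustment at 0.05. Standard errors are those implied by the F statistic, and intervals are approximate 95% intervals from them. CPM are normalised by the effective library size. The biological coefficient of variation was 22.6%.

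Before the data were examined, 33 gene lists were fixed, together with the tests, the alternatives and the rule for named genes. The lists came from general knowledge of the tissue and not from these samples. Members were matched by symbol and otherwise by a RefSeq synonym (GRCm38.p6 table, names only). The 25 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over lists at 0.05. Some genes belong to more than 1 list. Members are counted over all genes and adjusted over the list alone. The rule named Tet1, Tet2 and Tet3, the 12 largest rises and the 12 largest falls among called genes with an average log2 CPM of at least 1 and groups that did not overlap, up to 4 members per list by adjusted p, and the 5 widest regions in each direction. Col1a1, Gapdh and Xist were named after their values were seen. Some results for single genes are not reported here.

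The script was tested on simulated data for KO against WT with 3 libraries each, drawn for 9943 genes. Each gene was drawn independently at the dispersion trend for its level. Spread of genes around that trend and correlation between genes were left out. It called 59% of 100 genes changed 2-fold and 84% of 100 genes changed 4-fold, with 8 unchanged genes among 151 calls. Replicate libraries were compared by a chi-square over genes with at least 10 summed counts. It came to between 4.05 and 7.13 per degree of freedom within genotypes, above the value near 1 or less of libraries that differ by counting noise alone, so no libraries were merged. This does not show that they came from separate animals. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper quartile factors, other filters, a replicate block, leaving out each library, fry and an estimated correlation. An offset for genomic gene length, from start to end of the gene, was added after the data were seen. Not made were the comparison of regions by genomic feature and the overlap of regions with called genes, because the build of the coordinates is not stated.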

Results

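The series measured gene expression and DNA methylation in preadipocytes, the fat cell precursors of the stroma, from the inguinal white fat of male mice on a high fat diet. The cells were sorted as positive for PDGFRa and negative for CD45, CD31 and TER119, which excludes most immune, endothelial and red blood cells. Mice with floxed Tet3 alleles (Tet3 f/f, here WT) were compared with mice in which Tet3 was deleted in Pdgfra-expressing cells (here KO). TET3 is a dioxygenase that oxidises 5-methylcytosine. RNA-seq covered 3 WT and 3 KO libraries after 6 weeks of diet. Whole genome bisulfite sequencing (WGBS) covered 1 pool per genotype after 14 weeks of diet. The RNA libraries held between 1831218 and 2374978 counts over 35976 genes. In WT the totals were 2106900, 2374978 and 2002250 for libraries 1 to 3, and in KO they were 2014991, 1960587 and 1831218. At these depths a gene at 0 counts could lie at up to 1.27 to 1.65 CPM (read counts scaled to the size of the library), the worth of 3 counts, and such limits cover counting error only. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

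Tet3 was the targeted gene, and its counts check the genotype labels. WT libraries 1 to 3 held 93, 127 and 104 Tet3 counts, and KO libraries 1 to 3 held 76, 87 and 79. The normalised level was 49.9 ± 5.01 CPM in WT and 42.3 ± 2.91 CPM in KO (SD, n = 3 each). The log2 fold change of KO over WT was -0.24 ± 0.24 (SE), with an approximate 95% interval of -0.73 to 0.25, and edgeR gave an adjusted p of 0.71. The counts therefore did not separate the genotypes at Tet3. Counts per gene add up reads of deleted and retained exons, so they do not test the deletion itself. The other members of the family did not pass the test either. Tet1 had 11, 14 and 26 counts in WT and 45, 43 and 23 in KO (log2 fold change 1.27 ± 0.47, adjusted p = 0.154), and Tet2 stood at 54.8 ± 10.4 and 65.4 ± 7.30 CPM (SD, n = 3; adjusted p = 0.659).

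The comparison of KO with WT asked which genes change in preadipocytes when Tet3 is targeted. Sult1e1, which encodes estrogen sulfotransferase, rose from 36.9 ± 16.9 to 283 ± 47.0 CPM in KO (SD, n = 3 each), a log2 fold change of 2.92 ± 0.21 (SE). Cilp, which encodes a protein of the extracellular matrix, fell from 289 ± 39.4 to 45.5 ± 14.5 CPM, a log2 fold change of -2.67 ± 0.19. Both had an adjusted p of 7.59e-11. The other large falls included Col8a1, a chain of collagen VIII, at -3.26 ± 0.40, F3, which encodes tissue factor, at -2.99 ± 0.39, and Il34, a ligand of the CSF1 receptor, at -2.75 ± 0.41. Hmcn2, which encodes a hemicentin of the extracellular matrix, fell by 3.94 ± 0.82. Hmcn2 had 1, 2 and 1 counts in KO libraries 1 to 3, so the size of its fall is uncertain. The other large rises included Nptx2, a pentraxin, at 3.13 ± 0.66, Fam69c at 2.27 ± 0.41 and Slfn2, a Schlafen family gene, at 1.87 ± 0.34. Nptx2 had 3, 5 and 3 counts in WT libraries 1 to 3, so the size of its rise is uncertain too.

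In all, 357 of 9943 tested genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 181 higher and 176 lower in KO. Of these, 145 changed by at least 2-fold, 66 up and 79 down. In 348 of the 357 genes the WT and KO libraries did not overlap, where chance gives 10% of genes and 20.4% of all tested genes did so. Passing the test favours genes whose groups are separate, so the 348 are no further support for the calls. The rule for genes of largest change named 24, and 9 of them, those above, passed in every fit that left out 1 library. The other 15 lost their call in at least 1 such fit. Among the rises, leaving out 1 library took the adjusted p up to 0.226 for Pkp2, 0.145 for Cetn4, 0.235 for Hs3st3b1, 0.265 for Ifi44, 0.191 for Fndc5, 0.344 for Tlr5, 0.163 for 9330159F19Rik and 0.250 for Pex6. Among the falls it reached 0.0587 for Art3 without KO library 3 and 0.0684 for Tmem204 without WT library 2. It went up to 0.191 for Tmem246, 0.246 for Fam65c, 0.198 for Fblim1, 0.472 for P2rx7 and 0.343 for Fgf9. The lower group's mean was 0.792 CPM for Pkp2 and 5.27 CPM for Fgf9. The number of calls was 203 without WT library 1, 226 without WT library 2 and 158 without KO library 3, and 108 genes were higher in KO without WT library 3.

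**Figure D1:**
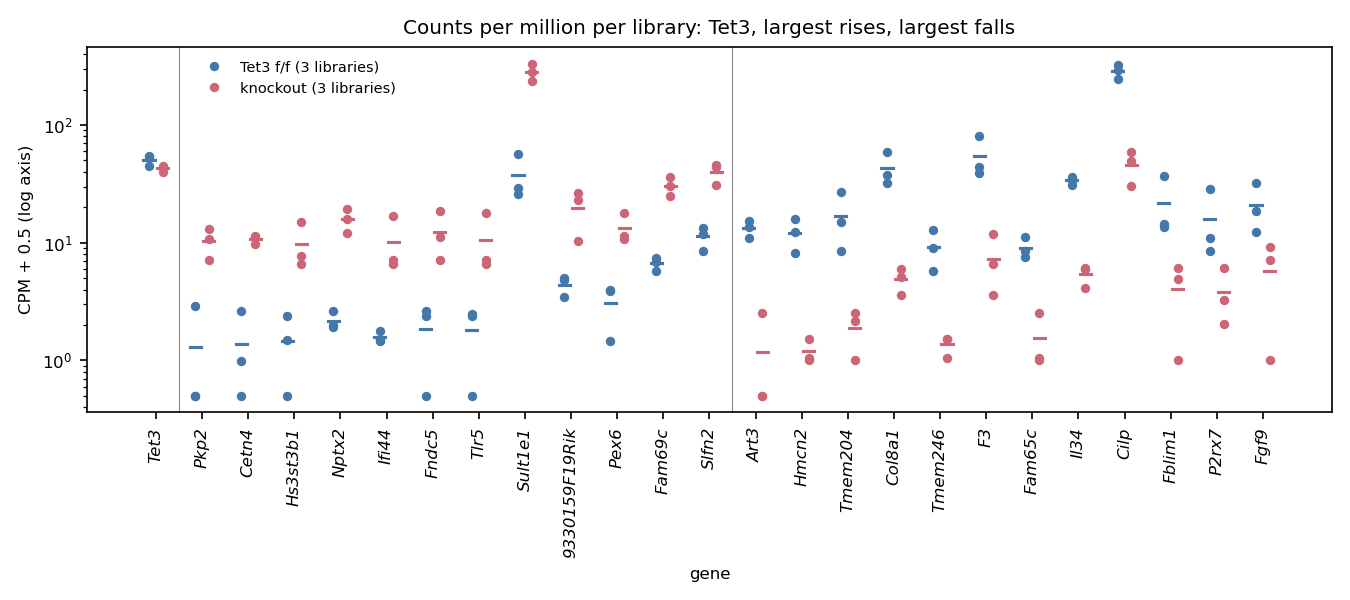
Normalised level of Tet3 and of the 24 genes of largest change, in CPM plus 0.5 on a log axis, with a point per library and a bar at the mean of the 3 WT or 3 KO libraries. WT and KO points do not overlap for any of the 24 genes, because the rule that named them required it. Tet3, which was named without that rule, lies at 49.9 CPM in WT and 42.3 CPM in KO.

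Genes of the interferon response were higher in KO. Of 35 tested members, 14 rose, 0 fell and 21 did not pass, and 22 rose when adjusted over the list alone. Irf7, a transcription factor that drives interferon genes, rose from 27.2 ± 2.39 to 74.7 ± 17.1 CPM (SD, n = 3), a log2 fold change of 1.46 ± 0.25 (SE, adjusted p = 0.000283). Irf1 rose by 0.78 ± 0.14, Rtp4 by 1.18 ± 0.22 and H2-K1, a class I histocompatibility gene whose reads could be shared with close relatives, by 0.65 ± 0.11. The median member had a log2 fold change of 0.75, and camera with a preset correlation gave the list an adjusted p of 2.39e-19. The call held with an estimated correlation (adjusted p = 0.0491). KO library 1 had the highest sum over the list, at 9812 CPM, and over erythroid markers, at 169 CPM. The interferon list summed to 7312 and 7836 CPM in KO libraries 2 and 3 and to 5905 ± 145 CPM in WT (SD, n = 3). Without KO library 1 the list still passed (adjusted p = 5.99e-13). Ifi44 kept its call only when KO library 2 was the library left out, with an adjusted p of up to 0.265 in the other 5 fits.

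Inflammatory and NF-kB genes were also higher in KO as a list, with 5 of 31 tested members up, 1 down and 25 not passing, and 9 up and 1 down when adjusted over the list alone. The camera adjusted p was 0.000586, but the call was lost with an estimated correlation (adjusted p = 0.295), under fry (adjusted p = 0.192) and without WT library 3 (adjusted p = 0.0501). The list summed to 13570 CPM in KO library 1, the highest of the 6, and to 10050 and 11487 CPM in KO libraries 2 and 3, and without KO library 1 the adjusted p was 0.0413. Cxcl13, a B cell chemokine, rose from 112 ± 16.9 to 306 ± 92.6 CPM (SD, n = 3; log2 fold change 1.45 ± 0.18). Complement C3 rose by 0.86 ± 0.11, Ptx3 by 0.95 ± 0.15 and Nfkbiz by 0.71 ± 0.12.

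Markers of preadipocyte states moved in opposite directions. Genes of Icam1-high committed preadipocytes were lower in KO, with 8 of 19 tested members down, 1 up and 10 not passing, and 11 down and 1 up when adjusted over the list alone (camera adjusted p = 9.31e-16). Mgp, matrix Gla protein, fell from 732 ± 102 to 219 ± 81.7 CPM (SD, n = 3; log2 fold change -1.74 ± 0.17). The chemokine gene Cxcl14 fell by 1.40 ± 0.16. Car3, which encodes a carbonic anhydrase of adipocytes, was the member that rose, by 1.62 ± 0.32. Genes of F3-high regulatory cells were lower too, with 7 of 13 tested members down, 1 up and 5 not passing, and 8 down and 2 up over the list alone (camera adjusted p = 2.00e-06). Mgp belongs to both lists. Besides F3, Fmo2 fell by 0.72 ± 0.16, while the imprinted transcript H19 rose by 1.46 ± 0.21. Genes of Dpp4-high interstitial progenitors were higher, with 5 of 20 tested members up, 0 down and 15 not passing, and 11 up over the list alone (camera adjusted p = 8.39e-08). Gfpt2 rose by 0.76 ± 0.12, from 371 ± 16.6 to 628 ± 13.4 CPM (SD, n = 3). Dpp4 itself was tested and did not pass over all genes. Pi16 rose by 0.53 ± 0.12, a call lost without WT library 2, WT library 3 or KO library 3 (adjusted p up to 0.0788). All 3 lists kept their call with an estimated correlation, at adjusted p of 0.0204, 0.0363 and 0.0287.

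Collagen genes fell as a list, with 8 of 20 tested members down, 1 up and 11 not passing, and 12 down and 2 up when adjusted over the list alone (camera adjusted p = 1.83e-09, and adjusted p = 0.0287 with an estimated correlation). Col4a1 and Col4a2, chains of basement membrane collagen, fell by 0.82 ± 0.10 and 0.76 ± 0.12, and Col6a3 by 0.59 ± 0.10. Col4a1, Col4a2 and Col15a1 also belong to the Icam1-high committed list, so the calls of these lists are not independent. Col1a1, chosen after its values were seen, rose by 0.44, a call lost without WT library 1 (adjusted p = 0.0710) or WT library 2 (adjusted p = 0.0578). Without KO library 1 the Col1a1 log2 fold change was 0.24 and still passed. The summed level of the collagen list was 67846, 71152 and 69386 CPM in WT libraries 1 to 3. It was 80124 CPM in KO library 1, above every WT library, and 62700 and 65573 CPM in KO libraries 2 and 3, below every WT library. The median member had a log2 fold change of -0.38. Genes of matrix remodelling were lower as well, with 9 of 36 tested members down, 2 up and 25 not passing, and 12 down and 5 up over the list alone (camera adjusted p = 0.000586). The call of the matrix remodelling list was lost with an estimated correlation (adjusted p = 0.0524). Biglycan (Bgn) fell from 1614 ± 162 to 849 ± 52.2 CPM (SD, n = 3; log2 fold change -0.93 ± 0.11) and elastin (Eln) by 0.75 ± 0.12, while Timp2, an inhibitor of metalloproteinases, rose by 0.50 ± 0.08. The summed level of the matrix list, which was not tested, lay higher in all 3 KO libraries, at 73177 ± 2129 CPM against 67467 ± 520 CPM in WT (SD, n = 3).

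**Figure D2:**
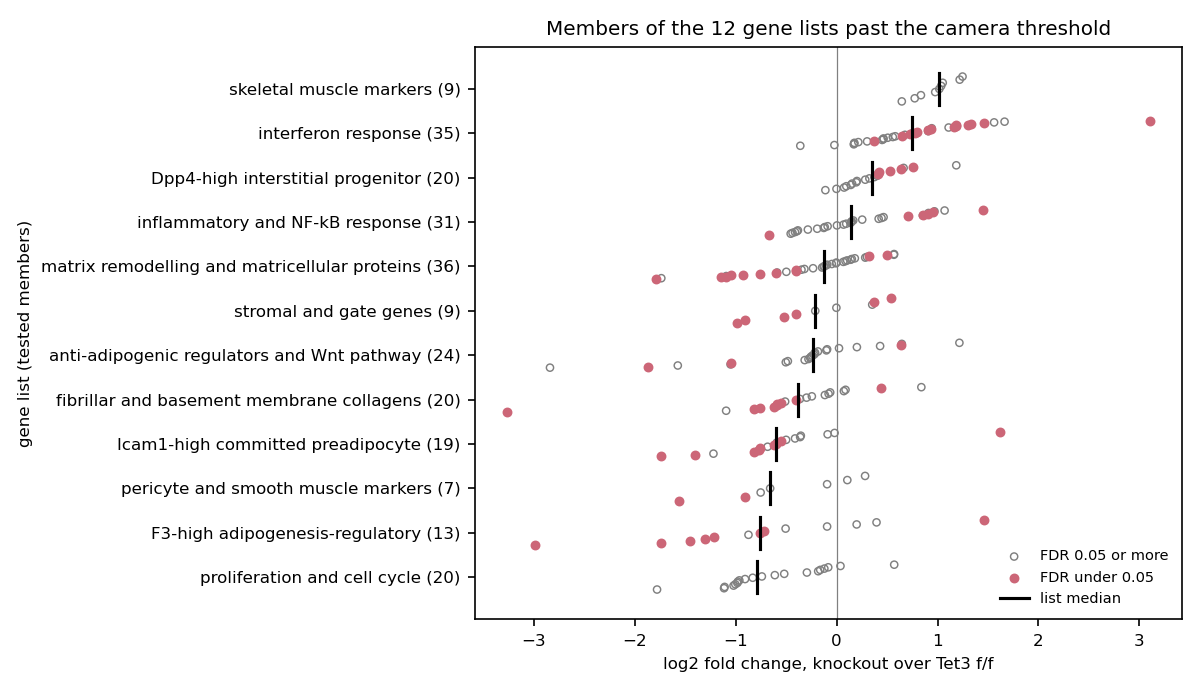
Log2 fold change of KO over WT for each tested member of the 12 gene lists past the camera threshold, with filled points for genes at an adjusted p under 0.05, open points for the rest and a vertical bar at the list median. The medians run from -0.78 for proliferation genes to 1.02 for skeletal muscle markers.

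Adipogenic transcription factors and commitment signals did not pass as a list (camera adjusted p = 0.13), with 4 of 26 tested members up, 1 down and 21 not passing, and 4 up and 2 down over the list alone. Klf4 rose from 2248 ± 94.1 to 3772 ± 371 CPM (SD, n = 3; log2 fold change 0.75 ± 0.09), Zbtb16 rose from 107 ± 6.87 to 216 ± 41.8 CPM and Cebpb, which acts early in adipogenesis, rose by 0.74 ± 0.17. Egr2 fell by 1.20 ± 0.30. The call of Cebpb was lost without WT library 2 or 3 or KO library 1 or 3 (adjusted p up to 0.0805), and that of Egr2 without WT library 2 or 3 or KO library 2 or 3 (adjusted p up to 0.113). Anti-adipogenic and Wnt pathway genes were lower (camera adjusted p = 0.0241), with 2 of 24 tested members down, 1 up and 21 not passing, and 4 down and 3 up over the list alone. The Wnt list's call was lost with an estimated correlation (adjusted p = 0.131), without WT library 2 (adjusted p = 0.0565) and without KO library 1 (adjusted p = 0.0512). Hes1, a target of Notch, fell by 1.05 ± 0.16, Dkk3 fell by 1.87 ± 0.30 and Klf2 rose by 0.64 ± 0.10. The Wnt list mixes ligands with inhibitors of Wnt signalling such as the Sfrp genes, so its direction does not measure Wnt activity. Proliferation genes were lower as a list (camera adjusted p = 0.00291), a call lost with an estimated correlation (adjusted p = 0.0748). Of these genes, 0 of 20 tested members passed on their own by edgeR, DESeq2 or limma-voom, or over the list alone by edgeR. At an unadjusted p under 0.05, 5 were lower and 0 higher. Mcm4, a replication helicase subunit, stood at 30.6 ± 7.68 CPM in WT and 15.5 ± 3.52 CPM in KO (SD, n = 3; adjusted p = 0.124).

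The remaining lists of pathways did not pass. Mature adipocyte and lipid storage genes had 2 of 21 tested members up and 1 down, with 4 up and 3 down over the list alone (camera adjusted p = 0.759). Lpl, lipoprotein lipase, fell from 5469 ± 178 to 3610 ± 1368 CPM (SD, n = 3; adjusted p = 0.0163), a call lost without WT library 1, WT library 3 or KO library 3 (adjusted p up to 0.135). TGF-beta, activin and BMP genes had 3 up and 3 down of 31, with 6 and 7 over the list alone (adjusted p = 0.448). Tgfbi fell by 1.03 ± 0.12 and Id3 rose by 0.62 ± 0.11. Insulin and IGF genes had 1 up and 4 down of 26, with 2 and 4 over the list alone (adjusted p = 0.341). Igfbp7 fell by 0.92 ± 0.12 and Igf2r, an imprinted receptor gene, from 224 ± 30.0 to 113 ± 14.1 CPM (SD, n = 3). Imprinted genes had H19 up and Igf2r down among 20, with 1 up and 2 down over the list alone (adjusted p = 0.838). Genes of DNA methylation and demethylation had Idh1 down among 21 tested, in both counts (adjusted p = 0.223), and the Idh1 call was lost when any library other than KO library 2 was left out (adjusted p up to 0.293). Glycolysis and hypoxia genes had Ddit4 up and Epas1 down among 23, in both counts (adjusted p = 0.616). The glycolytic genes Gapdh, Eno1 and Pgk1 had between 0 and 9 counts per library and were not tested, so this result leaves them out. The Ddit4 call was lost without WT library 3 or KO library 2 (adjusted p up to 0.0665). Oxidative phosphorylation genes had 1 of 37 down, and 3 over the list alone (adjusted p = 0.373). Senescence and p53 genes had Cdkn1a up among 19, in both counts (adjusted p = 0.165), a gene whose call was lost when any library other than KO library 2 was left out (adjusted p up to 0.214). The lists of cholesterol synthesis, of the unfolded protein response and of thermogenic genes had 0 members passing of 15, 24 and 5 (adjusted p = 0.902, 0.842 and 0.759), and 1 thermogenic gene rose over the list alone. DESeq2 and limma-voom called 0 of their members, and at an unadjusted p under 0.05 edgeR had 3 cholesterol, 2 unfolded protein response and 1 thermogenic gene. Median, mean and test differed in sign for mature adipocyte genes (median -0.0070, mean 0.012, tested up), for thermogenic genes (0.0027, -0.060, up) and for the unfolded protein response (0.014, -0.069, down).

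Genes induced by cell isolation, the immediate early and heat shock genes, went both ways, with 4 of 34 tested members up and 4 down, and 7 up and 5 down over the list alone (camera adjusted p = 0.545). Camera tests for a shared direction, so this p does not show that these genes were alike in WT and KO. Among the 34 members DESeq2 called 12 and limma-voom 10. Over all genes edgeR called 357 of 9943 (3.59%), DESeq2 364 of 7550 and limma-voom 335 of 9943. By each tool the called share was higher in this list than over all genes. Hspa1b fell by 1.05 ± 0.13, and Ier5, Klf4 and Klf2 rose. Macrophage markers summed to 17.5 ± 10.1 CPM in WT and 19.6 ± 2.60 CPM in KO, lymphocyte markers to 2.38 ± 1.67 and 1.60 ± 0.997 CPM and mesothelial markers to 3.52 ± 1.81 and 4.74 ± 1.45 CPM (SD, n = 3). With fewer than 5 members tested, these lists, those of endothelial, erythroid and Schwann cells, the germline genes and the sex chromosome check had no list test. Endothelial markers summed to 1357 ± 91.1 CPM in WT and 1758 ± 168 CPM in KO, of which Ly6c1, also a Dpp4-high gene, made 1167 and 1562 CPM. The Ly6c1 call was lost without WT library 1, 2 or 3 or KO library 1 (adjusted p up to 0.170). Schwann cell markers summed to 869 ± 26.9 and 877 ± 61.9 CPM. Germline genes summed to 15.8 ± 3.02 and 13.3 ± 2.59 CPM. Erythroid markers summed to 169 CPM in KO library 1, the library with the highest interferon sum, and to between 13.8 and 51.2 CPM in the other 5. Of the sex chromosome genes, Xist had 0 counts in 5 libraries and 2 in KO library 3, and 4 Y-linked genes were tested without a call. Gapdh, which most cells express highly, had 0 or 1 counts in each library, so a low count in these data does not by itself show absence. The reason for the low Gapdh counts was not tested.

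Skeletal muscle markers were higher in KO as a list (camera adjusted p = 0.000324), a call lost with an estimated correlation (adjusted p = 0.353) and under fry (adjusted p = 0.233). Of these markers, 0 of 9 tested members passed by edgeR, DESeq2 or limma-voom, or over the list alone by edgeR. At an unadjusted p under 0.05, 3 were higher and 0 lower. Their sum was 143, 39.4 and 157 CPM in WT libraries 1 to 3 and 142, 248 and 272 CPM in KO libraries 1 to 3. Pericyte and smooth muscle markers were lower (camera adjusted p = 0.000586), with 2 of 7 tested members down, 0 up and 5 not passing, and 3 down over the list alone. The pericyte list's call was lost with an estimated correlation (adjusted p = 0.0673), without WT library 1 (adjusted p = 0.0828) and without KO library 1 (adjusted p = 0.0552). Pdgfrb fell from 292 ± 27.0 to 155 ± 14.2 CPM (SD, n = 3; log2 fold change -0.91 ± 0.14) and Notch3 by 1.56 ± 0.32. Pdgfrb is also in the stromal list. The mural genes Rgs5, Acta2, Myh11, Cspg4 and Higd1b were too low to be tested and summed to 6.91 ± 3.01 CPM in WT and 8.82 ± 2.85 CPM in KO (SD, n = 3). Stromal and gate genes were lower (camera adjusted p = 0.0345), with 4 of 9 tested members down, 2 up and 3 not passing, and 4 down and 3 up over the list alone. The stromal list's call was lost with an estimated correlation (adjusted p = 0.169) and without KO library 2 (adjusted p = 0.0847). Pdgfra, the gate gene, fell from 648 ± 25.8 to 451 ± 38.6 CPM (SD, n = 3; log2 fold change -0.52 ± 0.12, adjusted p = 0.00598, and 0.0544 without WT library 1). Cd9 fell by 0.99 ± 0.16 and Cd34 rose by 0.54 ± 0.11. The summed level of the stromal list, which was not tested, lay higher in all 3 KO libraries, at 27322 ± 317 CPM against 26274 ± 351 CPM in WT (SD, n = 3).

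The WGBS comparison asked where methylation differs between the WT and KO pools. The authors' deposited table lists 1820 regions of difference between a first and a second group, and its columns do not name the genotype of either group. Of the regions in the authors' deposited table, 1811 were less methylated in the first group and 9 were more methylated, so 99.5% went the same way (exact 95% binomial interval 99.1% to 99.8%). With 1 pool per genotype there is no replicate check, the interval covers counting error over regions selected by the authors, and the read depth behind each difference is unknown. The absolute differences in the authors' deposited table ran from 30.3 to 73.1 percentage points with a median of 40.8, and 90 regions (4.95%) reached 50 percentage points. Region length ran from 201 to 1745 bp with a median of 337 bp, and regions held 6 to 70 CpGs with a median of 9, per the authors' deposited table. Together these regions cover 670125 bp and 18462 CpGs, 37 of them lie on chromosome X and 1 on chromosome Y in the authors' deposited table.

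Coordinates are given as in the authors' deposited table, whose genome build is not stated there; the submitters' notes list both mm10 and GRCm39, so no gene was assigned. The widest losses in the first group in the authors' deposited table lay on chromosome X. They were 73.1 percentage points at 53912574 to 53912840 (20 CpGs), 63.3 at 74518353 to 74518556 (7 CpGs) and 60.0 at 142467562 to 142468228 (9 CpGs). Next in the authors' deposited table came 58.0 percentage points on chromosome 10 at 110009569 to 110009945 (6 CpGs) and 57.9 on chromosome 8 at 47298088 to 47298375 (6 CpGs). The widest gains in the first group in the authors' deposited table were 69.6 percentage points on chromosome 6 at 104241112 to 104241324 (16 CpGs) and 61.9 on chromosome 5 at 110119277 to 110120061 (6 CpGs). They were followed in the authors' deposited table by 47.9 on chromosome Y at 90779569 to 90779840 (12 CpGs), 43.0 on chromosome 13 at 97985650 to 97985900 (19 CpGs) and 42.5 on chromosome 10 at 59218931 to 59219221 (20 CpGs).

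**Figure D3:**
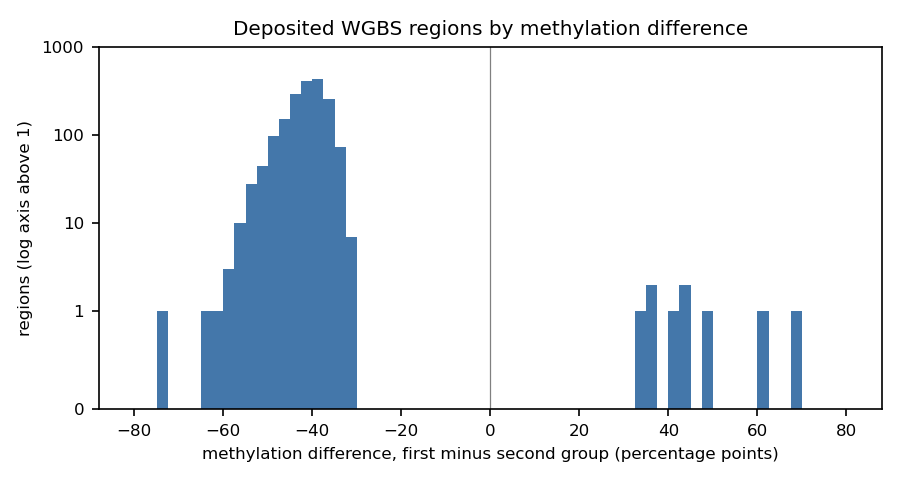
Number of regions in the authors' deposited table by methylation difference, the first minus the second group, in percentage points, on a count axis that is logarithmic above 1. The 1811 regions lower in the first group lie between 30.3 and 73.1 percentage points below 0, with a median size of 40.8, and 9 regions lie on the other side.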

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

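The offset for genomic gene length was chosen after the data were seen, and the other settings before. The total of 357 genes lay between 335 and 456 under DESeq2, limma-voom, RLE, upper quartile, other filters and the length offset, and 0 of the 357 changed direction. Leaving out 1 library gave 158 to 370 genes, 82 to 182 of them higher and 76 to 188 lower, with fewer samples in each fit. A 2-fold minimum left 145, 66 up and 79 down. Tet3 stayed between -0.33 and -0.18 without 1 library and did not pass in any fit. The labels do not say whether the replicate numbers pair the libraries. Same-numbered libraries correlated at 0.0203, 0.0169 and -0.000243 in their deviations, and WT and KO libraries of other numbers at -0.0583 to 0.0389. No pairing was seen. Deviations from means of 3 libraries hold these correlations near 0 on average, so a weak pairing cannot be excluded. A replicate block gave 501 genes, 251 up and 250 down, and changed no list call.

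Of the 12 lists past camera's threshold, 5 passed with an estimated correlation. It ended the calls of anti-adipogenic and Wnt genes (0.131), matrix remodelling (0.0524), inflammatory genes (0.295), proliferation (0.0748), pericyte and smooth muscle markers (0.0673), skeletal muscle markers (0.353) and stromal and gate genes (0.169), all adjusted p. Under fry, inflammatory genes (0.192) and skeletal muscle markers (0.233) lost their call and senescence genes passed (0.0354). Without 1 library the adjusted p ranged from 0.0215 to 0.0565 for anti-adipogenic and Wnt genes, from 4.69e-07 to 0.0501 for inflammatory genes, from 0.000289 to 0.0828 for pericyte markers and from 0.00784 to 0.0847 for stromal and gate genes. The cause was not tested. Of 128 named genes besides Tet3, 88 kept their side of the threshold in every setting that gave a value, and 0 called genes reversed.

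In the authors' deposited table, a difference of at least 1.5 times the smallest left 306 regions, 99.0% of them lower in the first group, by construction fewer. Leaving out chromosomes X and Y left 1782. Coverage and p-value thresholds for regions, the comparison by genomic feature and the overlap with called genes were not run. In data simulated with 3 libraries per genotype at the observed depths and dispersion trend, 59% of 2-fold changes were called. Genes were drawn independently and without spread around the trend, so the share may differ in the real data. How much of it is due to depth was not tested.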

Other observations

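The tests of library identity, depth and exons for Tet3, of immune and mural cells, of cell shares, of gene length, of gene families and of the ERK and Hedgehog lists were chosen after the values were seen. Of the 357 called genes, 266 belong to no fixed list, 137 higher and 129 lower in KO. The clearest by adjusted p after Cilp and Sult1e1, chosen after their values were seen, include Smoc2, a matricellular gene, which fell from 1230 ± 233 to 459 ± 99.8 CPM (SD, n = 3; log2 fold change -1.42, adjusted p = 5.77e-08), and Emp1, which fell by 1.08. Samhd1, a restriction factor, rose by 1.18, and Il1r2, the decoy receptor of interleukin 1, rose by 1.18. Ctsk, cathepsin K, fell by 1.03. Ifi27l2a rose by 1.72, although reads of a gene of this family can be split with its relatives. Among 294 families of genes grouped by the letters of their symbols, 3 passed camera at an adjusted p of 0.05, and 0 did with an estimated correlation. Collagens were lower (camera adjusted p = 0.000356), and the interferon-inducible families Gbp (0.00393) and Ifi (0.00451) were higher. In the Ifi family 2 of 9 tested genes were called up and 1 down. Families were drawn from all tested genes, including members of the fixed lists such as Col4a1 and Ifi44. They are therefore no separate support for the collagen and interferon lists.

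Feedback targets of ERK signalling and genes of the Hedgehog pathway were tested as hypotheses. Of 11 tested ERK feedback genes, Spry1 and Dusp6 fell and 0 rose. The camera p of that list was 0.251, which leaves the question open. The 10 tested Hedgehog genes had a median log2 fold change of -0.39. The camera p of the list was 0.0205 with the preset correlation and 0.0728 with an estimated one, so a lower Hedgehog response in KO may be present but is not settled.

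Tet3 counts did not fall past the test in KO. A swap of single libraries is argued against only by mean correlations. On average 0 of the 6 libraries correlated better with the other genotype than with their own, with a smallest margin of 0.00824. Single pairs overlapped, as WT library 3 correlated at 0.931 with KO library 2 and at 0.925 with WT library 2. A swap of all WT with all KO labels would leave these correlations unchanged, so they do not test it. Low depth is argued against for a loss of 2-fold, because the lower 95% bound of the log2 fold change was -0.73. Reads from exons left in the floxed allele, or from cells that kept the allele, could hold the gene count near the WT level, and at a log2 fold change of -0.24 over the whole gene this cannot be told apart from an undeleted gene, since counts per gene do not separate exons.

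Interferon genes were higher in KO. Immune cells carried into the KO libraries are argued against only as far as their markers were counted. The summed difference of macrophage and lymphocyte markers had an upper 95% bound of 15.6 CPM. That is 0.644% of the 2415 CPM that the interferon list gained. This bound covers cells within the sorted libraries only and says nothing of immune cells left in the fat. The markers lay near the floor, and Ptprc and Lyz2 had 0 counts in all 6 libraries. How much marker and interferon signal an immune cell brings was not measured, so the bound sets no exact limit on such cells. A trend with genomic gene length is argued against as the whole cause, because the trend fitted to the libraries was small: removing it moved the log2 fold change of tested genes by a median of 0.00725 and by up to 0.11, against a list median of 0.75 (adjusted p after it 4.46e-19). A segment carried along with the Tet3 allele stays open: 0 of the 14 called interferon genes lie among the 100 tested genes nearest Tet3 (gene order of GRCm38), but 0 tested members do, so this count decides nothing, and 5 of those 100 genes were called against 3.59% of all tested genes. A response to the loss of Tet3 may remain as a hypothesis, as may an untested difference between the animals or their handling.

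Committed, F3-high and collagen genes were lower while Dpp4-high genes were higher. The committed list shares members with the F3-high and the collagen list. A trend with genomic gene length is argued against as the whole cause, because the same fitted trend, at up to 0.11, lies below the smallest of the 4 list medians in size, 0.35 for Dpp4-high genes (largest adjusted p after it 8.19e-07), while transcript length was not tested for any list. Fewer mural cells stay open: Rgs5, Acta2, Myh11, Cspg4 and Higd1b reached in WT 0.134% of the CPM that the committed list lost, but they lie near the floor, and the whole mural list reached 10.1%. Other shares of preadipocyte subpopulations could give the pattern, as could changed levels within each cell. Of the members, 3 passed in the direction opposite to their list, and bulk libraries cannot separate shares from levels, so these cannot be told apart.

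The 9 regions that were more methylated in the first group of the authors' deposited table were denser in CpGs, at a median of 6.78 per 100 bp against 2.75 in the 1811 others. A two-sided permutation test over regions gave p = 1e-05, the smallest that 100000 resamples can give. The comparison of CpG density was not among those planned before the data were examined. Regions of 1 pair of pools are not replicates, and no explanation was tested.

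The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split with as many genes and the 1 split with as many lists. It called 357 genes and the highest of the other splits called 0. It called 12 lists, and the other splits called between 0 and 5. Each of the other splits puts libraries of both genotypes in both groups, so a genotype difference widens the spread within its groups. Few called genes are then likely in them, so their 0 is no measure of what chance gives.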
